A study of Homo sapiens with 4 samples.

How the data were processed

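RNA sequencing was compared between 2 groups of GATA2/eGFP-positive endothelial cells derived from the human embryonic stem cell line H1: wild type (WT, 2 libraries) and GFI1 knockout (GFI1-KO, 2 libraries). Per the labels' protocols, RNA was extracted with Trizol and libraries were made from total RNA with the Illumina TruSeq RNA Sample Prep Kit. The deposited table holds raw read counts per gene, as whole numbers, with a column for each library. Per the submitters' processing notes, HISAT2 2.0.4, SAMtools 1.3.1, HTSeq 0.6.0 and DESeq 1.18.1 were used with the builds hg38 and GRCh38; the notes as used here give no role or order. The annotation version, the read filters and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes may have been split or dropped. Of 19912 gene identifiers, 19902 were matched to GENCODE release 29 (GRCh38), which gave symbols, coordinates and exon overlaps; 19878 are protein-coding.

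Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Library totals were 2239214 and 2417410 counts for WT replicates 1 and 2, and 146584 and 2332621 for GFI1-KO replicates 1 and 2. A floor of 3 counts corresponds to 1.34, 1.26, 19.9 and 1.34 CPM (counts scaled to the library's TMM-adjusted total) in the same order. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

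Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr at its defaults (minimum count 10, minimum total count 15), and the quasi-likelihood functions glmQLFit and glmQLFTest with genotype as the model term. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 11380 genes tested were called changed. This version of glmQLFit fits by default an earlier form of the quasi-likelihood dispersion, and a newer form is an option. The design fixed before the data were examined names the functions without that option. The counts of calls under both forms had been seen when the choice was written out explicitly; the default was kept because it is the call as fixed, and the newer form's count is given beside it. Log2 fold changes are GFI1-KO over WT with a prior count of 0.125, and the standard error (SE) is the absolute unshrunken log2 fold change divided by the square root of F. CPM values are scaled by the TMM factors and given as mean ± SD of 2 libraries. Ratios of pooled counts carry exact 95% intervals.

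35 gene lists with 784 entries, of which 783 were found in the table, and the rule for named genes were fixed before the data were examined. The rule names GFI1, GFI1B and GATA2; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and both GFI1-KO libraries on the same side of both WT libraries; and up to 4 members per list with the smallest adjusted p, from which the text draws. Lists were tested with camera at a preset inter-gene correlation of 0.01 and at an estimated correlation, and with fry, each adjusted over 34 lists. These tests came from limma 3.58.1. With 2 libraries per genotype the estimated form has few residual degrees of freedom. A call lost with it therefore does not by itself show a correlation above the preset value.

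The scripts were tested on 20 simulated data sets of 11380 genes at the real depths of the GFI1-KO and WT libraries, with 200 genes changed. The edgeR test recovered 94.6% of 4-fold rises and 71.4% of 4-fold falls, and 35.1% of 2-fold rises and 24.1% of 2-fold falls. Of its calls, 7.31% were false, above the nominal 5%; with the newer dispersion 3.34% were false, with DESeq2 0.879% and with limma-voom 5.43%. Besides the 200 genes, the 25 pan-endothelial genes were shifted by 0.5 on the log2 scale in each data set and counted as changed. Camera at the preset correlation found this list in 20 of 20 simulations, with 6 calls of other lists. Simulated genes were drawn independently, so these counts do not cover lists whose genes are correlated. In the real data the estimated correlation reached 0.72, for S phase genes.

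Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, 3 other scalings, 2 other low-count filters, removal of the 20 most abundant genes, a minimum fold of 1.5, a replicate block and leaving out each library. The newer dispersion and random thinning of the 3 deeper libraries to 146584 counts (10 draws) were added after seeing the data. The replicate numbers are shared between genotypes, but nothing in the labels ties them to a common differentiation, so they were not used to pair samples.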

Results

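The transcriptomes of GATA2/eGFP-positive endothelial cells were compared between WT and GFI1-KO cells of the H1 human embryonic stem cell line, with 2 libraries per genotype. GFI1 is a transcriptional repressor active in the endothelial-to-haematopoietic transition, in which hemogenic endothelium gives rise to blood cells, and the comparison asks how the endothelial transcriptome differs without it. GFI1-KO replicate 1 held 146584 counts and the other 3 libraries held 2239214 to 2417410, between 15.3 and 16.5 times as many. The median count of a tested gene was 6 in that library and 86 to 91 in the others. Replication-dependent histone genes took 0.102% of its counts, against 0.000729% to 0.00157% in the other 3 libraries.

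GFI1 transcripts were lower in both libraries labelled GFI1-KO. GFI1 (ENSG00000162676; chromosome 1, 92474762 to 92486876, minus strand, GRCh38) was at 58.4 ± 0.12 CPM (counts scaled to the library's TMM-adjusted total) in WT and 19.7 ± 0.204 CPM in GFI1-KO (SD, n = 2 each), a log2 fold change of -1.57 (SE 0.31, edgeR adjusted p = 0.0215). The GFI1-KO values rest on 3 and 44 counts, and the pooled ratio was 0.336 with an exact 95% counting interval of 0.241 to 0.459. For GFI1-KO replicate 1 alone the interval was 4.10 to 58.1 CPM, which overlaps those of WT replicates 1 (48.9 to 69.4) and 2 (49.0 to 68.9). For GFI1-KO replicate 2 it was 14.2 to 26.3 CPM, below both. The labels do not say which part of the gene was altered, so the remaining reads do not tell whether protein was made. The call was lost without WT replicate 1 (adjusted p = 0.137), without WT replicate 2 (adjusted p = 0.096), without GFI1-KO replicate 2 (adjusted p = 0.271) and with DESeq2 (adjusted p = 0.443). GATA2 (chromosome 3, 128479427 to 128493185, minus strand), the gene whose reporter defined the sorted cells, fell from 273 ± 29.4 to 132 ± 10.6 CPM (log2 fold change -1.09, SE 0.24, adjusted p = 0.0376). Its call was lost without WT replicate 1 (adjusted p = 0.446), WT replicate 2 (0.0876) or GFI1-KO replicate 2 (0.131), with DESeq2 (0.129), with upper-quartile scaling (0.0518) and with the newer dispersion (0.0675). GFI1B, the paralog of GFI1, had a log2 fold change of -0.87 (SE 0.37, adjusted p = 0.433); its exons overlap those of TSC1.

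In GFI1-KO cells, genes of endothelial and arterial identity made up part of a set of changes that leaned upward, and the corepressor gene CBFA2T3 was among the largest falls. Of 11380 genes tested, 109 changed, 88 higher and 21 lower. For 105 of the 109, both GFI1-KO libraries lay on the same side of both WT libraries; this held for 41.2% of all tested genes, and chance gives 33.3%. The count was 58 (49 higher, 9 lower) with the newer quasi-likelihood dispersion and 33 (29 higher, 4 lower) with DESeq2. Without WT replicate 1 it was 62, without the shallow GFI1-KO replicate 1 it was 373, and without GFI1-KO replicate 2 it was 274; 35, 109 and 46 of the 109 genes were among them. Of the 21 lower genes, 12 had at most 3 counts in GFI1-KO replicate 1.

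Among called genes with a mean of at least 5 CPM, the largest rises were in FGF12, FILIP1, ZNF469, ZNF562, CDK10, FOXC1, HBEGF, CBLN1, ADGRF5 and ENTPD1. Their log2 fold changes ran from 3.50 for FGF12 to 2.52 for ENTPD1. PAX2, below that limit, had a larger one of 3.56 (SE 0.75, edgeR adjusted p = 0.027). ZNF469, a zinc-finger gene on chromosome 16, rose from 5.12 ± 3.45 to 47.2 ± 10.6 CPM (log2 fold change 3.30, SE 0.44, adjusted p = 0.00226). ADGRF5, an adhesion receptor gene, rose from 11.4 ± 1.64 to 73.3 ± 18.1 CPM (2.53, SE 0.34, adjusted p = 0.00226). ENTPD1, which encodes the ectonucleotidase CD39, rose from 9.68 ± 2.33 to 62.3 ± 15 CPM (2.52, SE 0.37, adjusted p = 0.00304). FOXC1, a forkhead transcription factor gene, had 2 and 17 counts in WT and 4 and 64 in GFI1-KO (2.76, SE 0.58, adjusted p = 0.0311). FGF12, FILIP1, ZNF562, CDK10, FOXC1, HBEGF and CBLN1 rest on 1 to 4 counts in GFI1-KO replicate 1. CDK10 shares exons with SPATA2L and AC010538.1, and ENTPD1 with AL365273.2 and an antisense gene. FILIP1 shares exons with AL080250.1 and AL445465.1, and ZNF562 with ZNF561-AS1.

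The largest falls were in SCGN, RBM46, WDR72, CBFA2T3, CAT, FGFBP3, PLEKHA7, RIPOR3, PRKCA and TNFRSF19. SCGN, which encodes the calcium-binding protein secretagogin, had 71 and 37 counts in WT and 0 and 2 in GFI1-KO, a pooled ratio of 0.0357 (exact 95% interval 0.00427 to 0.132). RBM46, an RNA-binding protein gene, had 73 and 66 counts against 0 and 3, a pooled ratio of 0.0416 (0.00848 to 0.124). CBFA2T3 (chromosome 16, 88874858 to 88977204) fell from 55.8 ± 8.26 to 7.76 ± 1.61 CPM (log2 fold change -2.67, SE 0.38, adjusted p = 0.00261). It had 138 and 119 counts in WT and 1 and 20 in GFI1-KO. The value in GFI1-KO replicate 1 lies below the floor of 3 counts, so the SD of 1.61 does not measure agreement between the libraries. CBFA2T3 shares exons with AC092384.2, RBM46 with AC009567.1, FGFBP3 with AL359198.1 and PLEKHA7 with OR7E14P. FGFBP3 fell from 360 ± 157 to 67.2 ± 20.1 CPM (-2.25, SE 0.32, adjusted p = 0.00261), and PRKCA, the protein kinase C alpha gene, had 89 and 93 counts in WT and 2 and 26 in GFI1-KO (-1.74, SE 0.38, adjusted p = 0.0372). CAT, which encodes catalase, had 38 and 45 counts in WT and 0 and 7 in GFI1-KO (-2.61, SE 0.58, adjusted p = 0.0409). Of the 10 rises and 10 falls, 4 and 5 stayed past the threshold without WT replicate 1, 7 and 7 without WT replicate 2, 10 and 10 without GFI1-KO replicate 1, and 2 of the 7 tested rises and 2 falls without GFI1-KO replicate 2. With the newer dispersion 8 and 7 stayed, with upper-quartile scaling 6 and 5, and with DESeq2 3 of 3 and 2 of 5 that had an adjusted p.

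**Figure D1:**
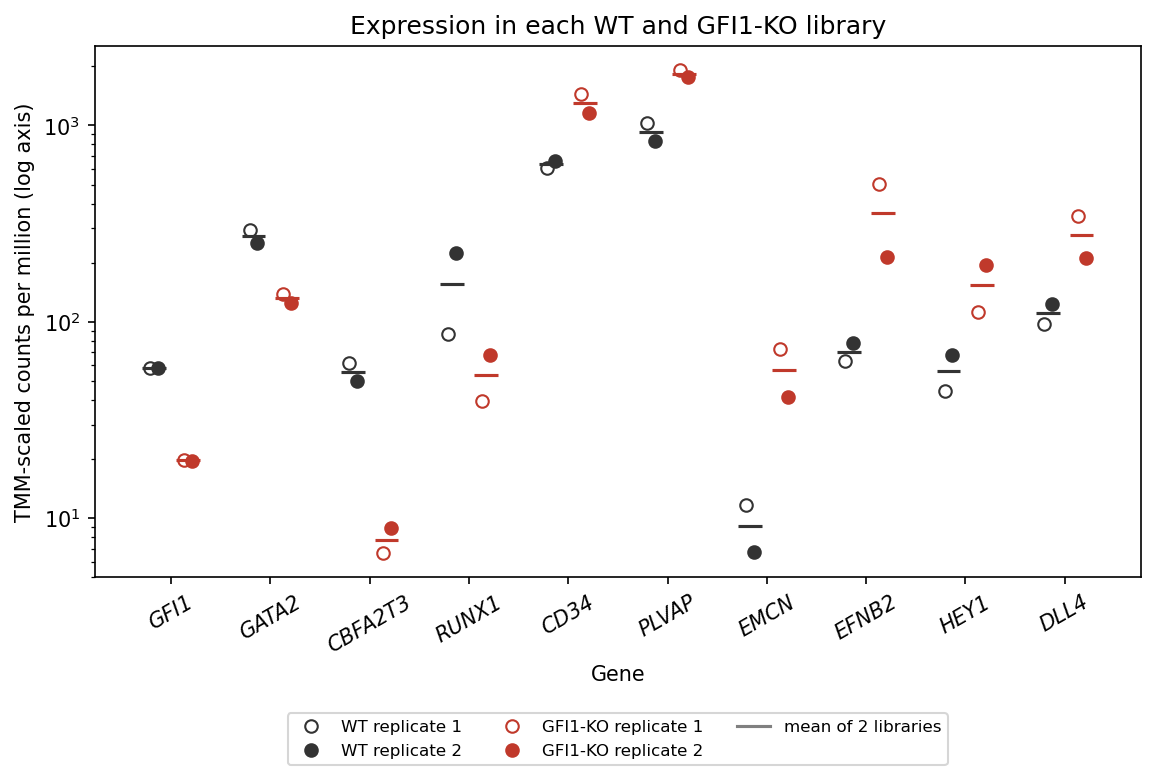
TMM-scaled CPM (log axis) of 10 genes in each library, with open and filled points for replicates 1 and 2 and a bar at the mean of each genotype. GFI1, GATA2 and CBFA2T3 lie lower in both GFI1-KO libraries than in both WT libraries, the 6 endothelial and arterial genes on the right lie higher in both, and RUNX1 in WT spans 87.1 to 225 CPM.

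Genes expressed across endothelium were higher as a list at camera's preset correlation, a call lost with an estimated one. Of 25 pan-endothelial genes tested, 5 rose, 0 fell and 20 did not pass, with 5 higher when adjusted over the list alone; the median log2 fold change was 0.47 and 22 of 25 values were above 0. EMCN, which encodes the sialomucin endomucin, rose from 9.16 ± 3.46 to 57.1 ± 22.3 CPM (log2 fold change 2.38, SE 0.41, adjusted p = 0.00959). CD34, a surface sialomucin of endothelial and haematopoietic progenitor cells, rose from 633 ± 34.6 to 1294 ± 203 CPM (1.02, SE 0.22, adjusted p = 0.0357). PLVAP, a component of endothelial diaphragms, rose from 931 ± 142 to 1835 ± 103 CPM (0.97, SE 0.22, adjusted p = 0.0416). ADGRL4 also rose (1.52, SE 0.29, adjusted p = 0.0177), from 66.9 ± 8.69 CPM in WT to 99.4 CPM in GFI1-KO replicate 1 and 235 CPM in replicate 2. The ADGRL4 call was lost with DESeq2 (adjusted p = 0.105) and the newer dispersion (0.0501). It was also lost without WT replicate 1 and without GFI1-KO replicate 2. S1PR1, named after its value was seen, rose as well (1.5, SE 0.33, adjusted p = 0.0424). Its 39.7 CPM in GFI1-KO replicate 1 lay between the WT values of 30.4 and 47.4. The S1PR1 call was lost with DESeq2 (adjusted p = 0.66), the newer dispersion (0.096) and upper-quartile scaling (0.0776). It was also lost without WT replicate 1 and without GFI1-KO replicate 2. CDH5 and KDR had log2 fold changes of 0.49 and 0.47 and PECAM1 of -0.33, with adjusted p of 0.439, 0.561 and 0.759. Camera at the preset correlation placed the list above other genes (adjusted p = 1.87e-10), and the adjusted p = 0.511 with an estimated correlation. Of the 5 calls, 1 remained without WT replicate 1, 3 without WT replicate 2, 5 without GFI1-KO replicate 1, 3 without GFI1-KO replicate 2, 3 with DESeq2, 2 with upper-quartile scaling and 1 with the newer dispersion.

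Arterial and Notch pathway genes were also higher as a list at the preset correlation alone. Of 21 tested, 4 rose, 0 fell and 17 did not pass, with 7 higher and 1 lower adjusted over the list alone, and the median log2 fold change was 0.40, with 17 of 21 values above 0. EFNB2, the arterial ephrin-B2 ligand gene, rose from 70.5 ± 10.1 to 359 ± 205 CPM (log2 fold change 2.18, SE 0.32, adjusted p = 0.00383) and passed in each fit that left out a library. The Notch target HEY1 rose from 56.1 ± 16.8 to 154 ± 58.2 CPM (1.59, SE 0.28, adjusted p = 0.0114), the receptor gene NOTCH4 from 36.9 ± 4.07 to 122 ± 43.5 CPM (1.52, SE 0.28, adjusted p = 0.0154) and the ligand gene DLL4 from 111 ± 18.7 to 278 ± 93.8 CPM (1.22, SE 0.26, adjusted p = 0.0372). HEY1 lost its call without WT replicate 1 (adjusted p = 0.138) or GFI1-KO replicate 2 (0.224), NOTCH4 without WT replicate 2 (0.0742), and DLL4 without WT replicate 1 (0.272), with DESeq2 (0.0536), upper-quartile scaling (0.0628) and the newer dispersion (0.0781). The gap junction gene GJA5, the lower member, had a log2 fold change of -1.15 (adjusted p = 0.055), and DKK2 of -1.21 (adjusted p = 0.508). NOTCH4 shares exons with GPSM3. The preset camera adjusted p = 4.59e-06, and the adjusted p = 0.511 with an estimated correlation of -0.021, below the preset 0.01.

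Transcription factors of blood commitment were lower as a list, again at the preset correlation alone. Of 13 tested, 0 rose, 1 fell and 12 did not pass, with 4 lower adjusted over the list alone; the median log2 fold change was -0.84 and 11 of 13 values were below 0. CBFA2T3 was the member that fell, and without GFI1-KO replicate 2 its adjusted p = 0.0549. The erythroid factor genes KLF1 and NFE2 had log2 fold changes of -2.66 (SE 0.69, adjusted p = 0.079) and -3.20 (SE 0.88, adjusted p = 0.0987), on 0 counts each in GFI1-KO replicate 1. RUNX1, required for the emergence of blood from endothelium, was at 156 ± 97.8 CPM in WT and 53.7 ± 19.7 CPM in GFI1-KO (-1.33, SE 0.38, adjusted p = 0.134). The preset camera adjusted p = 0.000124 and was 0.134 without GFI1-KO replicate 2; the adjusted p = 0.516 with an estimated correlation. Among 19 endothelial and hemogenic transcription factors, MECOM rose (2.18, SE 0.47, adjusted p = 0.0371; 12.3 ± 0.989 to 81.4 ± 62.9 CPM), 0 fell and 18 did not pass, with 5 higher adjusted over the list alone. MECOM was at 126 CPM in GFI1-KO replicate 1, on 19 counts, and at 36.9 CPM in GFI1-KO replicate 2, so its mean leans on the shallow library. It lost its call with upper-quartile scaling (adjusted p = 0.0673) and the newer dispersion (0.0877). MEIS1 and SOX17 had values of 1.08 (adjusted p = 0.0935) and 1.03 (adjusted p = 0.135). The list's median was 0.28 and its preset camera adjusted p = 0.00516, which became 0.783 without GFI1-KO replicate 2, where the median turned to -0.18. The adjusted p = 0.746 with an estimated correlation.

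**Figure D2:**
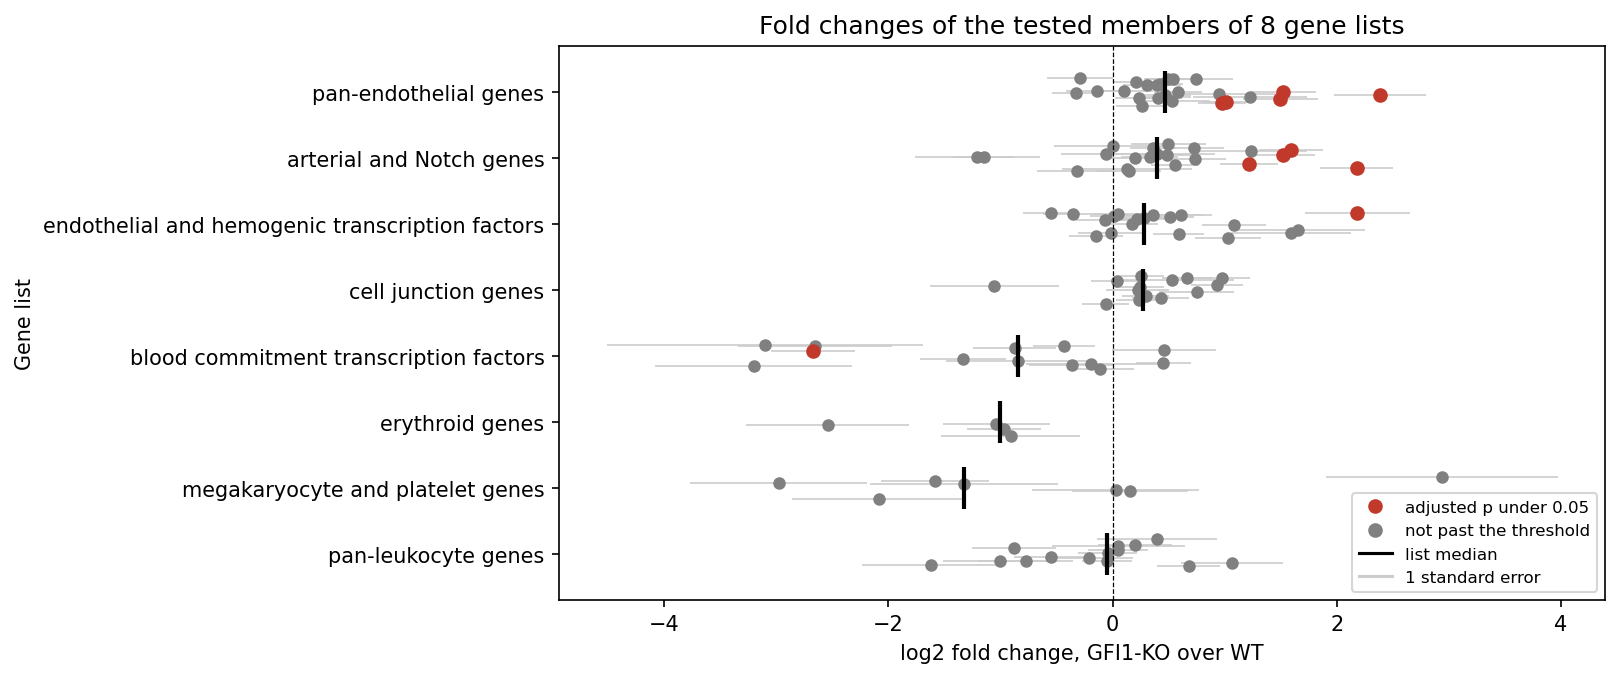
Log2 fold change (GFI1-KO over WT) of each tested member of 8 gene lists, with grey lines of 1 standard error, red points for adjusted p under 0.05 and black bars at list medians. Pan-endothelial and arterial medians lie at 0.47 and 0.40, and the medians of blood commitment, erythroid and megakaryocyte lists lie at -0.84, -1.0 and -1.32 with wider standard errors.

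The erythroid, megakaryocyte, leukocyte and myeloid marker lists held 0 calls over all genes. PTPRC, the pan-leukocyte CD45 gene, and 7 globin genes had 0 counts in all 4 libraries, which allows up to 1.34 CPM in each deep library and 19.9 CPM in the shallow library. These bounds hold for reads that were counted. The read filters are not given, so reads shared by similar globin genes may have been dropped. Of 4 erythroid genes tested, 0 passed over all genes and 2 were lower adjusted over the list alone; the median was -1.0 and the preset camera adjusted p = 0.00377, which was 0.297 without GFI1-KO replicate 2 and 0.0697 without WT replicate 2, and the adjusted p = 0.516 with an estimated correlation. Among 7 megakaryocyte and platelet genes, 0 passed, with 1 higher and 3 lower adjusted over the list alone. ITGA2B had a log2 fold change of -2.98 (adjusted p = 0.0893) and PF4 of 2.94 (adjusted p = 0.235). Both rest on few counts: ITGA2B had 17 and 46 in WT and 0 and 4 in GFI1-KO, and PF4 had 3 and 0 against 1 and 12. The list's median was -1.32 (camera adjusted p = 0.283). Without GFI1-KO replicate 1 the megakaryocyte list passed the preset camera (adjusted p = 0.00307) with 2 members lower, and with a mean of at least 5 CPM its adjusted p was 0.0481. The 14 pan-leukocyte and 3 myeloid genes held 0 calls, and 0 and 1 lower adjusted over the list alone, with medians of -0.046 and -0.10 and camera adjusted p of 0.422 and 0.363. Of 8 haematopoietic cytokine receptors, 0 passed; KIT had 0.99 (adjusted p = 0.248), the median was 0.36, and the preset camera adjusted p = 0.0446 was 0.984 without GFI1-KO replicate 1 (median -0.0080), 0.0844 without WT replicate 1, 0.394 without WT replicate 2, 0.175 without the low-count filter and 0.124 with limma-voom, and the adjusted p = 0.746 with an estimated correlation.

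Vascular and stromal lists held further single changes. Of 11 angiogenic sprouting genes, APLN (log2 fold change 2.12, SE 0.45, adjusted p = 0.0359) and HBEGF (2.66, SE 0.58, adjusted p = 0.0372) rose; both lost the call without WT replicate 1 (adjusted p = 0.168 and 0.462), APLN without GFI1-KO replicate 2 (0.976) and HBEGF without WT replicate 2 (0.604). APLN also lost it with DESeq2 (0.71), the newer dispersion (0.0708) and upper-quartile scaling (0.0665), and HBEGF with that scaling (0.0628). In GFI1-KO replicate 1 APLN was at 13.2 CPM, between the WT values of 6.70 and 17.6. The list's median was 0.22 (camera adjusted p = 0.0871). In the extracellular matrix list of 23, the collagen gene COL5A2 rose (1.35, SE 0.22, adjusted p = 0.00727) and COL18A1 fell (-1.24, SE 0.25, adjusted p = 0.0225); both lost the call without WT replicate 1 (adjusted p = 0.101 and 0.149), and COL18A1 with the newer dispersion (0.0647). COL18A1 shares exons with SLC19A1, which also fell (-1.07, SE 0.23, adjusted p = 0.0402) and was named after its value was seen. SLC19A1 lost the call without WT replicate 1 (0.395), WT replicate 2 (0.118) or GFI1-KO replicate 2 (0.0698), with DESeq2 (0.156), the newer dispersion (0.0675) and upper-quartile scaling (0.0534). The TGF-beta receptor gene ACVRL1 (1.01, SE 0.23, adjusted p = 0.0493) was the member of 22 TGF-beta and BMP genes that passed, and the adhesion molecule gene SELE (1.65, SE 0.36, adjusted p = 0.0372) the member of 10 NF-kappaB and inflammatory genes; both lost the call without WT replicate 1 (0.377 and 0.447) and without GFI1-KO replicate 2 (0.0812 and 0.368), and ACVRL1 without WT replicate 2 (0.433). They also lost it with DESeq2 (0.289 and 0.491), the newer dispersion (0.0708 and 0.0746) and upper-quartile scaling (0.0775 and 0.0637). The medians of the matrix, TGF-beta and NF-kappaB lists were 0.13, 0.20 and 0.27, and adjusted over the list alone 2, 3 and 1 members were higher and 1, 1 and 0 lower, with camera adjusted p of 0.422, 0.0701 and 0.281. Without GFI1-KO replicate 1 the angiogenic, matrix, TGF-beta and NF-kappaB lists passed the preset camera (adjusted p = 0.000315, 0.0299, 0.00937 and 0.0178). The angiogenic list also passed without WT replicate 1 (0.0386) or 2 (0.0448), and the TGF-beta list without WT replicate 1 (0.00879). Of 14 cell junction genes, 0 passed over all genes and 3 were higher adjusted over the list alone; TJP1 had 0.98 (adjusted p = 0.0744), the median was 0.27, the preset camera adjusted p = 0.0022, and the adjusted p = 0.516 with an estimated correlation.

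Of the other lists, 4 passed camera at the preset correlation without a member past the threshold. Cholesterol synthesis genes had a median of 0.27 with 23 of 24 values above 0 (adjusted p = 0.0022, and adjusted p = 0.779 with an estimated correlation). Without WT replicate 2 the median was -0.016 and the adjusted p 0.525, and without GFI1-KO replicate 2 the adjusted p was 0.102. The 3 neural genes had a median of 0.81 (adjusted p = 0.0117, and adjusted p = 0.561 with an estimated correlation), with 0.528 without GFI1-KO replicate 2 and 0.376 without the low-count filter. The 22 p53 target genes had a median of -0.41 (adjusted p = 0.0189, and adjusted p = 0.779 with an estimated correlation), and a median of 0.060 without WT replicate 1 (adjusted p = 0.717); without GFI1-KO replicate 2 the adjusted p was 0.935. The 13 mitochondrially encoded genes had a median of -0.25 (adjusted p = 0.00804, and adjusted p = 0.779 with an estimated correlation), with an adjusted p of 0.365 without GFI1-KO replicate 1, 0.0949 without WT replicate 2 and 0.144 without the 20 most abundant genes. The GFI1 cofactor complex, a repressor assembly that includes KDM1A and RCOR1, held 0 calls among 15 genes (median -0.073, camera adjusted p = 0.401). S phase, G2 and mitosis, chromatin modifier, HOX, pluripotency and ribosomal protein lists also held 0 calls, with medians of -0.15, 0.047, 0.16, 0.18, -0.12 and -0.11. Medians were 0.31 for venous and lymphatic, 0.13 for integrin and focal adhesion, 0.12 for interferon response, 0.45 for immediate early, -0.14 for hypoxia and glycolysis, 0.024 for unfolded protein and stress response and 0.044 for cardiac muscle genes. The mesenchymal and smooth muscle list had a median of -0.10 and a mean of 0.061 with an upward camera direction, and the epithelial and endoderm list a median of 0.041 with a downward direction. Adjusted over the list alone, 5 mesenchymal, 2 epithelial and endoderm, 2 neural, 1 venous and 1 hypoxia gene were higher, and 1 mesenchymal, 2 epithelial and endoderm, 1 hypoxia and 1 pluripotency gene were lower. These last 15 lists had preset camera adjusted p between 0.0511 and 0.729 and 0 called members. Of them, venous, integrin and ribosomal protein lists passed without GFI1-KO replicate 1 (adjusted p = 0.0052, 0.0191 and 0.00937). HOX, S phase, interferon and hypoxia lists passed without WT replicate 1 (7.16e-05, 1.22e-05, 0.0312 and 0.0386). Chromatin modifier and ribosomal protein lists passed without WT replicate 2 (0.0349 each), and the S phase list without GFI1-KO replicate 2 (0.0021). The immediate early list passed upward without GFI1-KO replicate 1 (1.67e-11) or WT replicate 2 (2.27e-10) and downward without WT replicate 1 (0.0398) or GFI1-KO replicate 2 (0.00847), and its adjusted p = 0.832 with an estimated correlation over all 4 libraries. With an estimated correlation 0 of 34 lists passed and 3 had an unadjusted p under 0.05. The estimates were 0.026 for pan-endothelial, -0.021 for arterial, 0.010 for cell junction and 0.0090 for blood commitment lists, near the preset 0.01. A much higher correlation therefore does not account for the loss of these calls. Of the other lists that passed at the preset value, estimates were 0.658 for p53 target, 0.622 for mitochondrially encoded and 0.556 for cholesterol synthesis genes. Endothelial and hemogenic transcription factors had 0.176, cytokine receptors 0.143, erythroid genes 0.0070 and neural genes 0.018. For lists with estimates far above 0.01 the preset adjusted p may be too small. With fry 0 passed, 3 had an unadjusted p under 0.05, and 9 passed fry's test for change in either direction.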

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

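The histone, S phase and poly(A) tests here were chosen after the histone counts had been seen; the outcome of the olfactory receptor test had not been seen when its prediction was written. Replication-dependent histone genes, none of which entered the test of genotypes, reached 1023 CPM (here per library total) in GFI1-KO replicate 1 (150 counts, exact 95% interval 866 to 1201), against 7.29 to 15.7 in the other 3 libraries. This was a signal outside the main measurement and above both WT libraries. Genomic DNA as the source is argued against, since 386 olfactory receptor genes together reached 54.6 CPM there (23.6 to 108), far below the 21 histone genes, although this too lay above the other libraries' 2.90 to 7.15. More cells in S phase is also argued against: the median log2 ratio of 24 S phase genes between GFI1-KO replicates 1 and 2 was -0.61 (interval from resampling genes -0.75 to -0.27). That interval treats the genes as independent, although their estimated correlation was 0.72, so it is too narrow. It also compares single libraries. Capture of RNA without poly(A) tails stays open and untested: 50 histone genes outside the list reached 1132 CPM against 7.72 to 12 elsewhere, which restates the histone signal, and of other RNA without such tails 0 genes were found to test it on. RNA quality was not tested, and because GFI1-KO replicate 2 did not share the signal, no link to genotype was seen.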

How the results depend on the processing

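The newer dispersion and the thinning were chosen after seeing the data. Genes changed, higher and lower numbered 109, 88 and 21, and were within 1.5 times of that with limma-voom, relative log expression scaling and without the 20 most abundant genes. They numbered 33, 29 and 4 with DESeq2, 58, 48 and 10 with upper-quartile scaling, 72, 57 and 15 with library totals only, 50, 43 and 7 with a mean of at least 5 CPM, 305, 216 and 89 without the low-count filter, 18, 13 and 5 with a minimum fold of 1.5, and 58, 49 and 9 with the newer dispersion. Leaving out each library gave 62 to 373 changed, 50 to 268 higher and 12 to 105 lower; where 1 GFI1-KO or WT library is left, it is assumed to vary like the other group. With a replicate block the counts were 327, 238 and 89; deviations of same-numbered libraries correlated at 0.116 over all tested genes and at 0.189 over the 1756 genes with at least 20 counts in the shallowest library, which with only 2 pairs does not show that the numbers pair samples. With the deeper libraries thinned to 146584 counts, edgeR called 0, 0 and 0 genes in the median and in each of 10 draws, and 176 genes had a median unadjusted p under 0.05, so depth limits the calls. The GFI1 log2 fold change was -1.58 with DESeq2 (adjusted p = 0.443), -1.57 with a minimum fold of 1.5 (adjusted p = 0.139) and -1.23 when thinned (adjusted p = 0.799), each no longer past the threshold, and -1.57 to -1.54 when a library was left out. Apart from the thinning, which changed depth alone, the causes of these differences between settings were not tested. Of 50 called genes checked one by one, all 50 kept their direction in every planned and added alternative that gave a value, and 7 kept their call in every planned one. Over all 109 calls, each tested gene kept its sign in each alternative except without GFI1-KO replicate 2, where 103 of 105 did. These genes were called from the same 4 libraries. The 3 other scalings moved the median of all genes by at most 0.024, against a smallest called change of 0.95. A kept sign under those scalings was therefore nearly fixed in advance. The preset camera calls of the pan-endothelial, arterial and cell junction lists held in all 15 alternative fits at the preset correlation, but 11 list calls, these 3 included, were lost with an estimated correlation (adjusted p = 0.511, 0.511 and 0.516 for the 3) and 11 with fry (0.272 for each of the 3). Among lists that did not pass, hypoxia and glycolysis genes passed in 10 of the 15 fits, immediate early genes in 6 (4 upward and 2 downward), angiogenic genes in 5 and S phase genes in 4. With the replicate block the p53 target list had a camera adjusted p of 0.108. List tests were not recomputed for the minimum fold. When a library was left out, the p53 target median ranged from -0.71 (without WT replicate 2) to 0.060 (without WT replicate 1), and the immediate early median from -0.86 (without GFI1-KO replicate 2) to 1.09 (without WT replicate 2), with -0.059 without WT replicate 1. The medians of endothelial and hemogenic transcription factors (-0.18, without GFI1-KO replicate 2), cholesterol synthesis genes (-0.016, without WT replicate 2) and cytokine receptors (-0.0080, without GFI1-KO replicate 1) fell below 0 while camera's direction stayed upward. The cause was not tested.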

Other observations

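The genes outside the lists, the immediate early ratios per library, the autosome and neighbour values, and the tests of shares, medians and spread in this part were chosen after results were seen; the fits without a library and with other scalings, and the lists, were planned. Single called genes outside the fixed lists, picked after their values were seen and not tested as a group, included these that were higher in GFI1-KO: ARHGEF15 (log2 fold change 2.50, SE 0.28, adjusted p = 0.000845), CLEC14A (2.22, SE 0.27, adjusted p = 0.00137), RAMP2 (1.61, SE 0.28, adjusted p = 0.0103), CD93 (1.20, SE 0.25, adjusted p = 0.0341) and THBD (1.31, SE 0.29, adjusted p = 0.0416). ARHGEF15, CLEC14A and RAMP2 passed in each fit that left out a library. KITLG, which encodes the ligand of KIT, rose by a log2 fold change of 1.87 (SE 0.33, adjusted p = 0.0101), TNFSF10 by 2.11 and LPL, the lipoprotein lipase gene, by 2.18. BTK (-1.53, SE 0.31, adjusted p = 0.0287) and PTGS1 (-1.23, SE 0.28, adjusted p = 0.0477) fell. Calls were lost for BTK without WT replicate 2 (adjusted p = 0.142), for PTGS1 without WT replicate 1 (0.54), WT replicate 2 (0.185) or GFI1-KO replicate 2 (0.464), for CD93 without WT replicate 1 (0.293) or 2 (0.0797), and for THBD without WT replicate 1 (0.789) or GFI1-KO replicate 2 (0.22). KITLG lost its call without WT replicate 2 (0.0623) or GFI1-KO replicate 2 (0.138), and TNFSF10 without WT replicate 1 (0.0765) or GFI1-KO replicate 2 (0.0637). With DESeq2 the adjusted p was 0.234 for BTK, 0.586 for PTGS1, 0.11 for CD93, 0.491 for THBD, 0.156 for KITLG, 0.0818 for TNFSF10 and 0.53 for LPL; with the newer dispersion it was 0.0688 for BTK, 0.0781 for PTGS1, 0.0619 for CD93 and 0.0888 for THBD. With upper-quartile scaling CD93 (0.0548), THBD (0.0683) and PTGS1 (0.067) lost their calls as well.

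The median log2 ratio of 22 immediate early genes over WT was -0.62 in GFI1-KO replicate 1 and 0.73 in GFI1-KO replicate 2. The list's median was 1.09 without WT replicate 2 and -0.059 without WT replicate 1, so WT replicate 2 lay above WT replicate 1. With the replicate block the median was 0.13 (preset camera adjusted p = 0.601). Without GFI1-KO replicate 1 it was 0.73, in a fit that sets GFI1-KO replicate 2 against both WT replicates. With all 4 libraries 0 of the 22 genes were called, with a preset camera adjusted p of 0.358. With all 4 libraries the list's estimated inter-gene correlation was 0.572, far above the preset 0.01, and the adjusted p = 0.832 with that estimated correlation; fits that left out a library were not run with it. The preset camera adjusted p was 0.0398 without WT replicate 1 and 0.00847 without GFI1-KO replicate 2, both downward, and 2.27e-10, upward, without WT replicate 2. Autosome medians of the log2 fold change lay between -0.081 on chromosome 21 and 0.018 on chromosome 7; an extra copy of a chromosome in all cells would give 0.58. Of 14 tested genes within 1 Mb of GFI1, edgeR called 0, with a smallest adjusted p of 0.377 and a median of -0.020.

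More genes rose than fell, 88 against 21. At an unadjusted edgeR p under 0.05, 661 were higher and 403 lower, and the median log2 fold change of all tested genes was -0.024. The shallow library as the whole cause is argued against, since without GFI1-KO replicate 1 71.8% of 373 calls were higher (exact 95% interval 67.0% to 76.4%). That interval treats genes as independent, and the fit leaves 1 GFI1-KO library, so it does not cover variation between samples. Depth may still add to the lean, which was not tested. In simulated data at these depths 94.6% of 4-fold rises and 71.4% of 4-fold falls were recovered. Equal depths were not simulated, so this gap cannot be assigned to the shallow library. Library scaling stays open: over 3 other scalings the lowest share was 79.2% (68.0% to 87.8%), but these moved the median of all genes by at most 0.024, against a smallest called change of 0.95, too little to test it. Relief from repression by GFI1 stays open as a hypothesis that expression data alone do not test.

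Of the pan-endothelial genes 5 of 25 were called higher, and of the blood transcription factors 1 of 13 lower. Both lists passed camera at the preset correlation in these directions, but not with an estimated correlation (adjusted p = 0.511 and 0.516) or with fry (0.272 and 0.351). The shallow library alone is argued against, since without it the pan-endothelial median was 0.52 (interval from resampling genes 0.39 to 0.66) and that of blood transcription factors -0.85 (-2.64 to -0.26). That fit leaves 1 GFI1-KO library, and the intervals do not cover variation between samples. Without GFI1-KO replicate 2 instead, the medians were 0.35 and -1.04. The variance of the pan-endothelial fold changes was 3.85 times that given by their standard errors (Q over its degrees of freedom, 95% limit 1.52). This argues against a rise by 1 common fold. A larger share of endothelial cells in the sort would give a common fold only for genes that the other sorted cells lack. Their expression there was not measured, so a larger endothelial share stays open. For the blood transcription factors the variance ratio was 6.94 against a limit of 1.75, which argues against a fall by 1 common fold. Some of these factors are also expressed in endothelium, so a loss of blood cells that acts unevenly on them stays open. A changed mix of endothelial subtypes or a shift of the gate with the fall of GATA2 stays open too. An effect of the genotype on the endothelial program also stays open; it was not itself tested.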
